A study of Mus musculus with 12 samples.

How the data were processed

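Gastrocnemius muscle, the large calf muscle of the hind limb, was taken from 12 anesthetized mice aged 32 weeks and frozen in liquid nitrogen. Per the labels' protocols, 100 mg of muscle was collected per mouse, RNA was isolated with Trizol, and 2 µg of RNA entered each library, made with an NEBNext Ultra RNA kit, which does not mark the strand of a transcript. The samples formed 4 groups of 3 mice, named wild type (WT), KO, P32L and R287Q after their Gmppb allele. The labels give no sex, litter, feeding state, hour of collection or batch. All 12 libraries showed transcripts of the Y-linked gene Ddx3y (10.0 to 14.5 TPM), and the transcript Xist stayed at or below 0.0241 TPM.

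The file held 1 value per gene symbol and mouse. The authors deposited these as log2 values: 2 raised to each value, less 1, summed to between 997591 and 998739 in every library, the total of a table in TPM, a unit that divides reads by transcript length and scales each library to the same sum. The values were therefore read as log2(TPM + 1), with a maximum of 16.7. FastQC, HISAT2, StringTie and DESeq2 are named per the submitters' processing notes, with the mouse build mm10. Their versions and the annotation are not given in the sources used here, nor is any adjustment made before deposit, which the word adj in the name of the table leaves open. The table held 30488 gene symbols. Of its values, between 23.9% and 30.3% per library were listed at 0, which can be an absent transcript or a failed estimate. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting interval is given. TPM is also a share of each library's total: mitochondrially encoded transcripts took between 53.0% and 58.4% of it, and 7 nuclear copies of mitochondrial genes another 19.6% to 21.0%, so all other genes share what remains. Genes were placed by symbol with GENCODE M21 on mm10, which matched 29334 symbols (96.2%).

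The design had been written for TPM, and the pseudocount it fixed, 1, was the one already in the deposited log2 values. Genes with a mean of at least 1 TPM over the 12 libraries, 9152 in all, were tested with limma 3.58.1 (R 4.3.3), with an intensity trend, on group means over all 12 libraries, so that the 4 groups shared 1 estimate of the spread. This gave 8 residual degrees of freedom and 3.11 prior degrees of freedom. The 6 comparisons were each mutant line with WT and the lines with each other. Adjusted p is Benjamini-Hochberg over the 9152 genes of a comparison, two-sided, and a call is an adjusted p under 0.05. A log2 fold change is the difference of mean log2(TPM + 1), which understates the change of genes near or below 1 TPM. For Gmppb, an exact two-sided permutation test was added, whose smallest possible p with 3 against 3 mice is 0.1.

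Gene lists for pathways, muscle states and other cell types, 41 in all, were written from textbook knowledge before the data were examined, as were the tests, the alternatives and the rule for named genes. Of these, 38 had at least 4 measured genes; the lymphocyte, epidermis and sex-linked lists did not and were not tested. Lists were tested with camera from limma, with its preset correlation of 0.01 between genes, adjusted over the 38 lists; camera with an estimated correlation and fry were run beside it. Within a list, p-values were also adjusted over the list alone. A list score of a library is the mean over the list's genes of its log2(TPM + 1) less the mean of the 12 libraries.

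The named genes were, per comparison with WT, Gmppb, the 10 genes that rose and the 10 that fell most among called genes with no overlap between groups and a symbol that is not a predicted model. Where fewer than 5 passed in a direction, the genes with the smallest unadjusted p up to 5 were added and are reported as not passing. Of each list called by camera, the 3 members with the smallest p in its direction were named, and the 5 highest and 5 lowest by the same rule between lines. Called genes outside the rule are named and said to be so.

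The procedure was tested on simulated data. For the recovery of planted changes, noise was drawn independently for each gene with its fitted spread, so correlation between genes was left out. In 10 simulated data sets with 200 changed genes among the 9152 of each comparison, the share of 1.5-fold changes that was called was 48.2% for KO with WT, 45.8% for P32L with WT and 43.0% for R287Q with WT. Of 2-fold changes 79.0%, 82.8% and 79.8% were called, and of 4-fold changes 93.8%, 94.2% and 93.4%. False calls made up 4.76%, 5.42% and 4.57% of the calls. These shares hold for 200 changed genes and independent noise. With fewer changed genes the adjustment is stricter, so fewer changes of a given size would be called, and this was not simulated. Another 100 simulated data sets without any group effect were made from the residuals of the 12 libraries and kept the correlation between genes. In these, camera with its preset correlation called a median of 12 to 13 of the 38 lists in each of the 6 comparisons. With an estimated correlation it called a median of 0. Limma called a median of 0 genes in each comparison, with rare bursts: for R287Q with WT the mean was 57.1, the 95th percentile 180.5 and the maximum 1903, and for R287Q with KO 22.2, 121.55 and 742. The maximum was 1109 for KO with WT and 1172 for P32L with WT.

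Alternatives were pseudocounts of 0.1 and 0.01, no filter or a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, mitochondrial genes left out, limma without trend, with robust variance or with weights per library, the 2 compared groups alone, the replicate number as a block, a minimum absolute log2 fold change of 1, and each library left out in turn. Added after seeing the data were mitochondrial genes left out together with their nuclear copies, protein-coding genes only, and the slow-fibre score as a covariate. Figures were drawn with matplotlib 3.10.9.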

Results

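Gene expression was measured by RNA sequencing in the gastrocnemius muscle of 12 mice at 32 weeks, 3 in each of 4 groups. Gmppb encodes GDP-mannose pyrophosphorylase B, which makes GDP-mannose, a precursor of the mannose in the glycans of alpha-dystroglycan and in N-linked glycans. The series asks how GMPPB bears on muscle. WT mice were compared with 3 engineered lines. Per the labels, KO mice are heterozygous for a Cas9 deletion of exons 2 and 3 (303 bp). P32L mice are heterozygous for a substitution at base 95 that changes residue 32 from proline to leucine. R287Q mice are homozygous for a substitution at base 860 that changes residue 287 from arginine to glutamine. Values are TPM, given as mean ± SD with n = 3 mice per group; depth is unknown. Profiles correlated at 0.984 to 0.992 between mice of a group and at 0.974 to 0.991 between mice of different groups, over genes, which are not independent replicates.

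The edited gene itself was checked in every library. Gmppb (chromosome 9, 108049242 to 108052801, plus strand, mm10) was at 4.42, 3.02 and 3.61 TPM in the 3 WT mice and 3.37, 3.62 and 3.33 TPM in KO. It was at 3.57, 3.55 and 3.26 TPM in P32L and 3.03, 4.09 and 4.16 TPM in R287Q. Its log2 fold change against WT was -0.07 in KO (95% interval -0.33 to 0.19, exact permutation p = 0.8), -0.06 in P32L (-0.32 to 0.20, exact permutation p = 0.7) and 0.02 in R287Q (-0.24 to 0.28, exact permutation p = 0.9). The smallest exact p this test can give is 0.1. None passed limma (adjusted p = 0.956, 0.999 and 0.993). In KO mice the interval reaches down to a log2 fold change of -0.33. A gene-level TPM covers all exons and does not show the deleted stretch apart, nor a base substitution, so it does not check the labels of any line. In the coding transcript of GENCODE M21, exon 2 starts at 108049512 and exon 3 ends at 108049841, a span of more than 303 bp. A single stretch of 303 bp therefore cannot remove both exons in full as numbered there. Rnf123, on the other strand, and Gm20529 overlap the end of Gmppb, and reads of an unstranded library from there cannot be assigned to one gene.

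**Figure D1:**
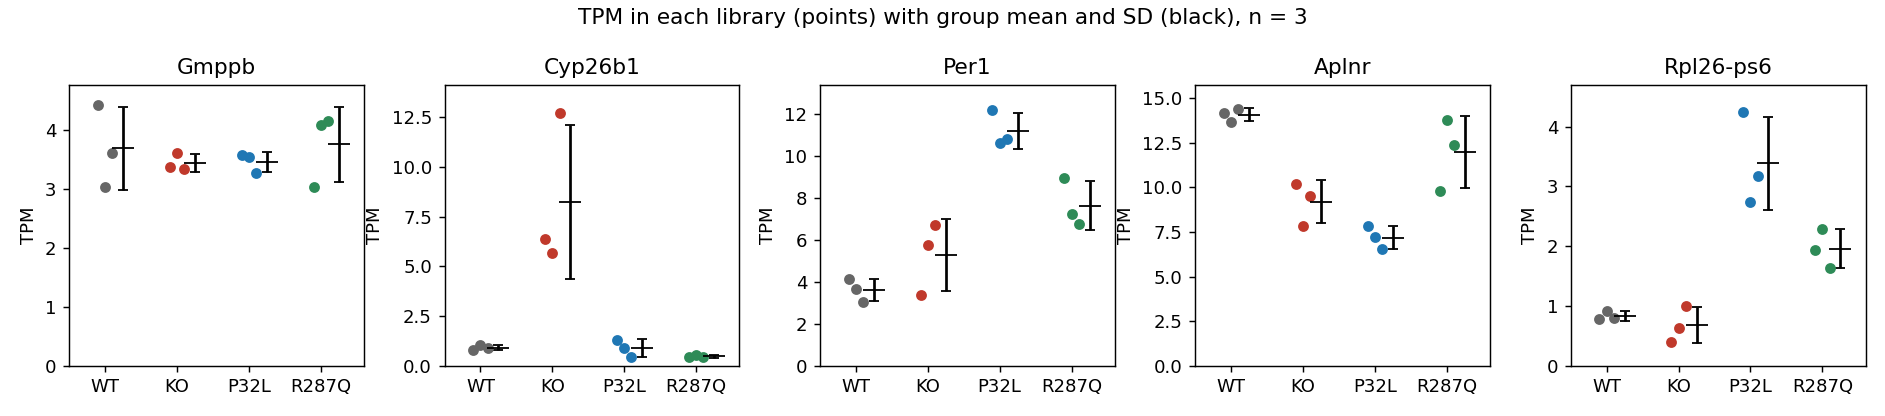
TPM of Gmppb and of 4 genes called in comparisons with WT, in each of the 3 mice of each group (points), with the group mean and SD (black). Gmppb lies between 3.02 and 4.42 TPM in all groups. Cyp26b1 lies between 5.65 and 12.7 TPM in KO mice and between 0.776 and 1.03 TPM in WT mice, and Per1 between 10.6 and 12.2 TPM in P32L mice and between 3.05 and 4.11 TPM in WT mice.

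In KO muscle, Cyp26b1, which encodes an enzyme that breaks down retinoic acid, rose to 8.24 ± 3.88 TPM from 0.903 ± 0.124 TPM in WT. The KO mice had 6.36, 5.65 and 12.7 TPM and the WT mice 0.776, 1.03 and 0.906 TPM, a log2 fold change of 2.20 (SE 0.24, limma adjusted p = 0.0133). Cyp26b1 (chromosome 6, 84571414 to 84593908, minus strand) was the 1 gene of 9152 called, and 545 genes (5.95%) had an unadjusted p under 0.05. The groups did not overlap for 720 genes, or 7.87%, where chance gives 10%. Among genes that did not pass, the lowest p on the higher side belonged to Flvcr1, a membrane transporter of heme and choline (log2 fold change 1.46, adjusted p = 0.366), and Cebpb, a transcription factor of inflammatory and adipocyte programs (1.08, adjusted p = 0.366). Next came Sat1, which acetylates polyamines (0.49, adjusted p = 0.366), and Ear2, a ribonuclease of eosinophils (1.09, adjusted p = 0.366). On the lower side these were Fam217b (-0.38, adjusted p = 0.209), Flnc, the actin crosslinker filamin C of the Z-disc (-0.50, adjusted p = 0.317), and Aplnr, the apelin receptor (-0.57, adjusted p = 0.421). The ribosomal RNA transcript Rn18s (-0.57, adjusted p = 0.436) and Mplkip (-0.30, adjusted p = 0.436) followed. The Cyp26b1 call was lost without WT replicate 1 (adjusted p = 0.130) or WT replicate 3 (adjusted p = 0.106). It was also lost in 4 of 14 other settings, over which its adjusted p ran from 0.000924 to 0.246. Its log2 fold change was lowest, 1.88, without KO replicate 3.

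Of the gene groups in KO muscle, markers of macrophages and monocytes had the lowest p by camera with its preset correlation. All 14 of 14 measured members were higher than in WT, with a mean log2 fold change of 0.79. Of these, 9 passed when adjusted over the list alone while 0 did over all genes. Cd14, a co-receptor for bacterial lipopolysaccharide, averaged 8.83 ± 2.02 TPM against 4.96 ± 1.35 TPM. The pore-forming Mpeg1 averaged 9.31 ± 2.84 against 4.47 ± 1.68 TPM, and the lysosomal protease Ctss 2.09 ± 0.667 against 0.877 ± 0.458 TPM. Immediate-early genes, which neural activity, stretch and tissue handling induce within minutes, were higher for 18 of 18 members (mean log2 fold change 0.79, 7 adjusted over the list alone, 0 over all genes). Their score was 0.98 in KO replicate 2, against -0.13 and 0.32 in KO replicates 1 and 3. Fos was at 1.94 (SE 0.53), Ier2 at 1.18 (SE 0.34) and Egr2 at 1.03 (SE 0.29). All 52 ribosomal protein genes lay above WT by a mean of 0.14, led by Rps27a at 0.87 (SE 0.30), but 0 passed over the list alone or over all genes. The mechanical stress list went the other way, with 11 of 12 members lower and a mean of -0.38. It had Flnc as the 1 member past the threshold over the list alone and 0 over all genes. Camera called these 4 lists (adjusted p = 4.33e-12, 2.12e-10, 1.1e-06 and 0.0002), but with an estimated correlation the calls were lost (adjusted p = 0.595, 0.595, 0.882 and 0.595 with an estimated correlation).

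Camera called 16 of the 38 lists in KO, 13 higher and 3 lower, within the range of 7.95 to 20 lists (5th to 95th percentile) seen in data simulated without an effect. The other higher lists were fibro-adipogenic progenitors (12 of 12 members higher), interferon response (12 of 12), nuclear genes of respiratory complex I (36 of 36) and of the other complexes (39 of 40). Fatty acid oxidation (27 of 28, with Pdk4, which turns muscle from glucose to fat, at 1.54) was also higher, as were matrix and fibrosis (22 of 24), erythroid (5 of 5), Schwann cell and nerve (6 of 6), muscle atrophy (12 of 15) and heat shock (10 of 13). Smooth muscle and pericyte markers were lower for 8 of 10 members and tenocyte markers for 7 of 7. Of these 12 lists, muscle atrophy had 1 member past the threshold over its list alone and 0 over all genes, the ubiquitin ligase Trim63 (0.36, SE 0.09), and the other 11 had 0. In the endoplasmic reticulum stress list, which was not called (camera adjusted p = 0.0901), Chac1, which degrades glutathione, was higher over the list alone (2.53, SE 0.55), 1 member against 0 over all genes. The adjusted p of the 12 lists ran from 0.595 to 0.882 with an estimated correlation, and camera that way and fry's directional and mixed tests each called 0 of the 38 lists. The mean of the macrophage list was 0.44 without WT replicate 2, still called by camera. The mean of the nuclear genes of complexes II to V turned to -0.00408 without WT replicate 3. The range of the macrophage score was wide within WT mice, from -1.04 in WT replicate 2 to 0.21 in WT replicate 1. WT replicate 2 also scored lowest of the 12 mice for fibro-adipogenic progenitor, interferon response, matrix and fibrosis, erythroid and heat shock genes.

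In P32L muscle, Per1, a repressor of the circadian clock that is also induced by glucocorticoids, rose 3.11-fold to 11.2 ± 0.846 TPM from 3.60 ± 0.528 TPM (log2 fold change 1.41, SE 0.18, adjusted p = 0.0308). Rpl26-ps6, a processed pseudogene of the ribosomal protein gene Rpl26, rose to 3.39 ± 0.771 TPM from 0.831 ± 0.0760 TPM (1.25, SE 0.15, adjusted p = 0.0306). Aplnr, the apelin receptor of vascular endothelium, fell to 7.19 ± 0.642 TPM from 14.1 ± 0.376 TPM (-0.88, SE 0.12, adjusted p = 0.0418). Gm17024, an intronic transcript on the strand of its host gene Ifrd1 and outside the naming rule, rose by 0.90 (adjusted p = 0.0308), with reads that Ifrd1 can share. Per1 lies on chromosome 11 (69095217 to 69109960, plus strand), Aplnr on chromosome 2 (85136225 to 85139923, plus strand) and Rpl26-ps6 on chromosome 9 (43217122 to 43217555, plus strand), and a pseudogene can take reads from its parent gene. These 4 were the genes called by limma, 3 higher and 1 lower, while 597 genes (6.52%) had an unadjusted p under 0.05. The groups did not overlap for 843 genes, or 9.21%, where chance gives 10%.

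Just outside the threshold in P32L lay Irs2, a docking protein of the insulin receptor that fasting induces, at 8.89 ± 1.14 against 3.83 ± 0.559 TPM (1.03, adjusted p = 0.0505). The nuclear receptor Nr4a3 (1.16, adjusted p = 0.0759) and Trim63, which tags sarcomere proteins for breakdown (0.52, adjusted p = 0.0862), did not pass either. On the lower side the endothelial lectin Clec14a (-0.39, adjusted p = 0.139), Septin4 (-0.40, adjusted p = 0.185), Glt28d2 (-0.24, adjusted p = 0.213) and Eid2 (-0.48, adjusted p = 0.217) did not pass. The count depended on the setting. Limma called 0 genes with the pseudocount at 0.01, with mitochondrial genes and their nuclear copies left out, or without WT replicate 1, WT replicate 3, P32L replicate 1 or P32L replicate 3. It called 1 without WT replicate 2, none of the 4 above, 1 without P32L replicate 2, Rpl26-ps6, and 7 without R287Q replicate 1. Per1, Aplnr and Gm17024 no longer passed on leaving out any WT or P32L library or with the slow-fibre score as a covariate. Their log2 fold changes stayed near those above over all settings (Per1 1.32 to 1.64, Aplnr -0.97 to -0.82, Gm17024 0.80 to 1.36). By contrast, 23 genes (15 higher, 8 lower) were called after median-of-ratios scaling and 28 (18 higher, 10 lower) after quantile normalization. With no filter 13 genes were called, but Per1, Aplnr and Gm17024 were not among them.

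Clock genes, which keep the daily rhythm of muscle, were examined as a group in P32L. Of 15 measured members, 11 were higher, with a mean log2 fold change of 0.28. Adjusted over the list alone Per1, Ciart (0.98, SE 0.22), Per2 (0.57, SE 0.13), Dbp (0.50, SE 0.13) and Nr1d2 (0.24, SE 0.08) were higher and Bhlhe41 (-0.47, SE 0.16) lower, 6 in all, against 1 over all genes. Camera called the list (adjusted p = 0.000151), but not with an estimated correlation (adjusted p = 0.540 with an estimated correlation). Fry's mixed test, which asks whether members change in either direction, gave an adjusted p of 4.24e-06. Immediate-early genes were higher for 18 of 18 members (mean 0.86, 7 adjusted over the list alone, 0 over all genes), Fos by 2.16 (SE 0.53). Heat shock genes, which encode protein-folding chaperones, were higher for 13 of 13 (mean 0.70, 6 over the list alone, 0 over all genes), among them Dnaja1 (0.89), Hspa8 (0.46) and Hsp90aa1 (0.81). Both were called by camera (adjusted p = 9.72e-14 and 5.18e-08) and not with an estimated correlation (adjusted p = 0.540 and 0.559 with an estimated correlation).

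Atrophy genes were higher for 12 of 15 members in P32L (mean 0.33). Of these, Trim63, Klf15, a glucocorticoid-induced factor (0.47, SE 0.10), and Fbxo32, the ligase atrogin (0.46, SE 0.12), passed adjusted over the list alone, against 0 over all genes. Camera called the list (adjusted p = 8.39e-06; adjusted p = 0.540 with an estimated correlation), and fry's mixed test gave an adjusted p of 0.000415. Lipid synthesis genes were lower for 11 of 16 members (mean -0.05), of which Insig1 (-0.41, SE 0.09), a sterol sensor, and the desaturase Scd2 (-0.47, SE 0.11) passed over the list alone and 0 over all genes (camera adjusted p = 0.0299; adjusted p = 0.912 with an estimated correlation). Slow-fibre genes lay lower for 13 of 13 members (mean -0.96), but 0 passed over the list alone or over all genes (camera adjusted p = 1.8e-05; adjusted p = 0.912 with an estimated correlation). P32L replicate 3 had a slow-fibre score of -1.83 against -0.22 and -0.07 in the other P32L mice, and without it the list mean was -0.40. Of endothelial markers 7 of 9 were lower, with Kdr, a receptor of vascular endothelial growth factor, past the threshold over the list alone (-0.46, SE 0.11) and 0 over all genes.

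Camera called 13 lists in P32L, 6 higher and 7 lower, where simulation without an effect gave 8 to 19. Besides those above, nuclear genes of complex I (31 of 36 lower) and of the other respiratory complexes (36 of 40 lower) were called. So were tenocyte (7 of 7 lower), smooth muscle and pericyte markers (7 of 10 lower), endoplasmic reticulum stress (18 of 20 higher, with Chac1 at 1.93) and macrophage markers (13 of 14 higher), all with 0 members past the threshold over each list alone. For these 6 lists and the endothelial list, adjusted p ran from 0.559 to 0.912 with an estimated correlation. That test and fry's directional test called 0 of the 38 lists, and fry's mixed test called 2, clock and atrophy. The macrophage list turned to a mean of -0.09 without WT replicate 2, from 0.27. The lipid synthesis mean turned to 0.03 without WT replicate 3 and 0.08 without P32L replicate 3, and that of complex I to 0.00279 without WT replicate 1.

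**Figure D2:**
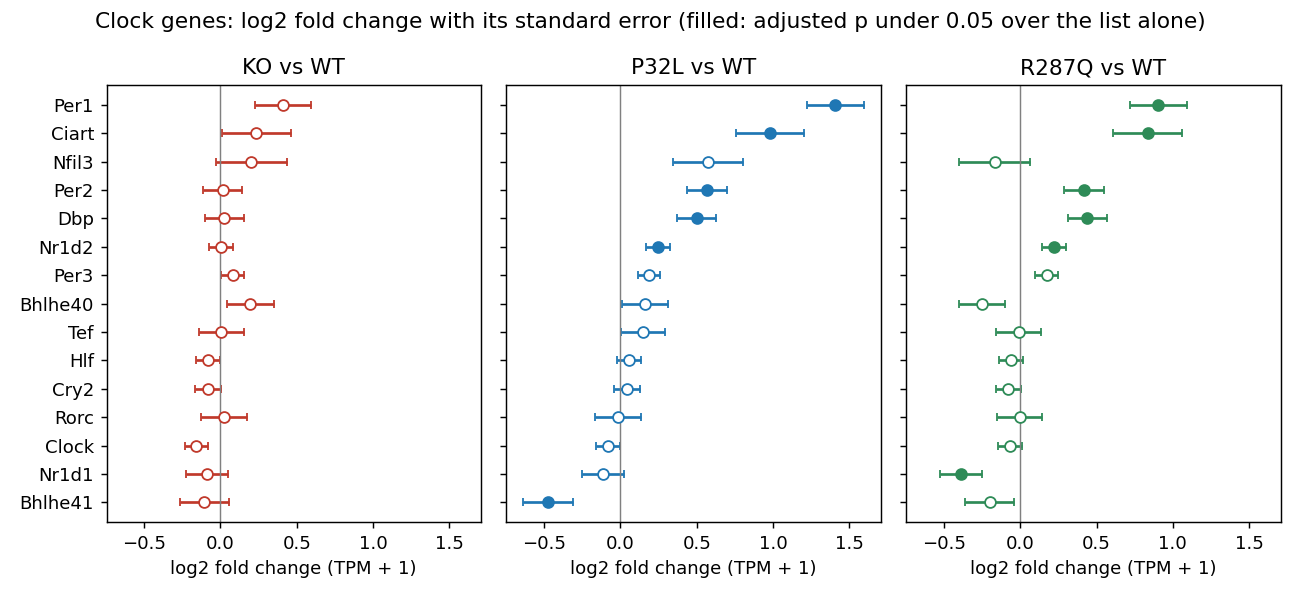
Log2 fold change of log2(TPM + 1) against WT (horizontal axis) for the 15 measured clock genes (vertical axis) in KO, P32L and R287Q mice, n = 3 per group, with bars of 1 standard error; filled points passed when adjusted over the list alone. Per1, Ciart, Per2, Dbp and Nr1d2 lie right of 0 and are filled in P32L and in R287Q, and no point is filled in KO.

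In R287Q muscle, limma called 0 of 9152 genes (lowest adjusted p = 0.425), with 491 genes (5.36%) at an unadjusted p under 0.05. Limma without trend and with robust variance also called 0. The groups did not overlap for 824 genes, or 9.0%, where chance gives 10%. The lowest p on the higher side belonged to Arrdc2, an arrestin-domain protein, at 22.5 ± 5.39 against 6.61 ± 2.05 TPM (log2 fold change 1.64, SE 0.33, adjusted p = 0.425), and Per1 at 7.62 ± 1.16 against 3.60 ± 0.528 TPM (0.90, SE 0.18, adjusted p = 0.425). The tetraspanin Tspan4 (0.40, adjusted p = 0.425), Rpl26-ps6 (0.69, adjusted p = 0.425) and the microRNA gene Mir703 (1.10, adjusted p = 0.441) followed. On the lower side these were the microRNA gene Mir6955 (-0.90), Cpeb2, which controls translation (-0.43), the pseudogene Rpl36a-ps2 (-0.62), the linker histone gene H1f4 (-0.69) and Smtnl2 (-0.41), all at an adjusted p of 0.425. Mir703 (98475556 to 98475664 on chromosome 5) and Mir6955 (78891840 to 78891913 on chromosome 15) are short. TPM divides reads by length, so few reads can give such values. The count of 0 became 34 with no filter. It became 81 (34 higher, 47 lower) with weights per library, a fit that stopped before converging and gave R287Q replicate 2 a weight of 6.65. It became 3 (2 higher, 1 lower) after median-of-ratios scaling, 1 (higher) after quantile normalization and 1 (lower) without KO replicate 1.

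The clock list in R287Q carried 6 members past the threshold over the list alone, against 0 over all genes: Per1, Ciart (0.83, SE 0.22), Dbp (0.44, SE 0.13), Per2 (0.42, SE 0.13) and Nr1d2 (0.22, SE 0.08) higher, and Nr1d1 (-0.39, SE 0.14) lower. Its mean was 0.12 and its median -0.01, with 6 of 15 members higher, so these differ in sign (camera higher, adjusted p = 0.0132; adjusted p = 0.914 with an estimated correlation; fry's mixed test, adjusted p = 2.13e-05). Fatty acid oxidation genes were higher for 25 of 28 members (mean 0.26). Of these, Ucp3, a mitochondrial carrier (0.89, SE 0.22), and Pdk4 (1.67, SE 0.44), both induced by fasting, passed over the list alone and 0 over all genes (camera adjusted p = 2.61e-08; adjusted p = 0.914 with an estimated correlation). Of lipid synthesis genes, a list not called by camera (adjusted p = 0.180), members lower when adjusted over the list alone included Scd2 (-0.50), Idi1 (-0.29) and Insig1 (-0.29), against 0 over all genes. In the myogenesis and regeneration list, not called by camera but called by fry's mixed test (adjusted p = 0.000965), Actc1, the cardiac actin of immature fibres (1.62, SE 0.39), and H19, an imprinted RNA (0.79, SE 0.22), were higher over the list alone, 2 against 0 over all genes.

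The other lists camera called in R287Q were neutrophil (4 of 4 members higher, mean 1.66), adipocyte (11 of 11, Plin4 at 0.58), interferon response (11 of 12), macrophage (13 of 14), matrix and fibrosis (19 of 24, with Ccn2 at 0.98), muscle atrophy (12 of 15) and proteasome (29 of 31 lower), all with 0 members past the threshold over the list alone. Their adjusted p was 0.914 with an estimated correlation, and that test and fry's directional test called 0 of the 38 lists, while fry's mixed test called 2, clock and myogenesis. In all, 9 lists were called, 8 higher and 1 lower, where simulation without an effect gave 7 to 19. The adipocyte score was 0.69 and 0.99 in R287Q replicates 1 and 2 and -1.20 in replicate 3, against -0.84 to 0.49 in WT. Plin4 did not follow this score in R287Q replicate 3, where it was at 64.8 TPM, against 40.3 to 46.0 TPM in WT. The neutrophil score was 1.79 and 2.25 in R287Q replicates 1 and 2 and -0.78 in replicate 3, with S100a9 at 9.37 ± 8.24 TPM against 0.676 ± 0.236 TPM in WT. The macrophage list turned to a mean of -0.11 without WT replicate 2, from 0.25. WT replicate 2 also had the lowest score of the 12 mice for interferon response (-0.44) and for matrix and fibrosis (-0.34).

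**Figure D3:**
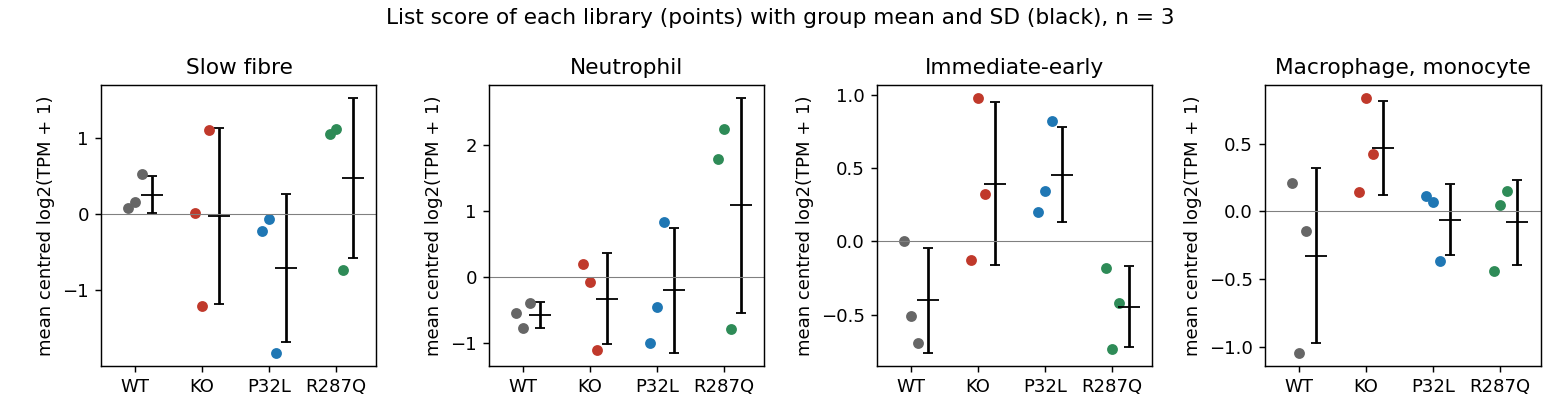
List score of each mouse (points; the mean over a list's genes of log2(TPM + 1) less the mean of the 12 libraries) with the group mean and SD (black), n = 3 per group. The slow-fibre score runs from -1.83 to 1.12 and the neutrophil score from -1.10 to 2.25, with mice of 1 group on both sides of 0 in KO and R287Q.

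Lists tied to the enzyme and to the dystroglycan pathway were not called by camera in any of the 6 comparisons. Genes of alpha-dystroglycan glycosylation, 9 measured, had a mean log2 fold change of -0.11 in KO, -0.07 in P32L and -0.14 in R287Q (camera adjusted p = 0.101, 0.419 and 0.143). Those of mannose and dolichol supply, 13 measured, had 0.07, -0.03 and -0.02 (adjusted p = 0.359, 0.511 and 0.421). For N-glycan assembly, 14 measured, the mean was -0.03, -0.01 and -0.06 (adjusted p = 0.359, 0.617 and 0.441). For the dystrophin complex and basal lamina, 17 measured, it was -0.04, -0.02 and -0.01 (adjusted p = 0.253, 0.338 and 0.602). Myogenesis and regeneration genes, 10 measured, gave 0.13, 0.11 and 0.13 (adjusted p = 0.944, 0.848 and 0.813), with medians of -0.06, -0.03 and -0.10 and a test direction of lower in KO and higher in P32L and R287Q, so mean, median and test differ in sign. The test direction was also opposite to the mean for mannose and dolichol supply and for the dystrophin complex in R287Q. The median of alpha-dystroglycan glycosylation in P32L was 0.01, against its negative mean. A list that is not called is not shown to be the same in the groups.

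The lines were then compared with each other, which tests whether these groups of mice differ. KO and P32L mice are heterozygous and R287Q mice homozygous, so comparisons with R287Q do not separate allele from zygosity. Litter, batch and hour of collection are not known for any line. Cyp26b1 was lower in P32L than in KO, at 0.882 ± 0.436 TPM (log2 fold change -2.24, SE 0.24, adjusted p = 0.00556), and lower in R287Q than in KO, at 0.462 ± 0.0621 TPM (-2.58, SE 0.24, adjusted p = 0.00269). Rpl26-ps6 was higher in P32L than in KO (1.39, SE 0.15, adjusted p = 0.00556). Against KO, R287Q also had less of the predicted genes Gm7846 (-0.84, adjusted p = 0.0105) and Gm10269 (-0.63, adjusted p = 0.0264) and more of Gm43980 (0.69, adjusted p = 0.0431), named outside the rule. Gm43980 overlaps Tra2a on the other strand, so their reads cannot be told apart. That made 2 calls for P32L with KO, where 733 genes had an unadjusted p under 0.05, and 4 for R287Q with KO, where 726 had. Limma called 0 genes between R287Q and P32L (lowest adjusted p = 0.0625, 610 genes at an unadjusted p under 0.05). With only the 2 groups in the fit, the calls between P32L and KO were lost.

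Named genes between lines that did not pass included, for P32L with KO, Irs2 (0.92, adjusted p = 0.143), Per1 (0.999, adjusted p = 0.174), Insig1 (-0.47, adjusted p = 0.200) and Scd2 (-0.56, adjusted p = 0.215). For R287Q with KO they included Wsb1 (-0.46, adjusted p = 0.119), the phosphatase gene Dusp10 (-0.52, adjusted p = 0.119), Jcad, a junction protein of endothelium (0.37, adjusted p = 0.156), and the endothelial exchange factor Arhgef15 (0.50, adjusted p = 0.156). For R287Q with P32L they were led by Trdj2, a joining segment of a T-cell receptor (-1.56, adjusted p = 0.0746), and Fos (-2.91, adjusted p = 0.196). Trdj2 is short (54136779 to 54136837 on chromosome 14), so few reads can give its values, which were 0, 0 and 0.549 TPM in R287Q. Aplnr (0.66, adjusted p = 0.196), the chemokine receptor Cxcr4 (0.62, adjusted p = 0.196) and the transferrin receptor Tfrc (0.54, adjusted p = 0.203) did not pass either. Per1 was not shown to differ between R287Q and P32L (-0.50, adjusted p = 0.665).

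By camera, 12 lists differed between P32L and KO (3 higher, 9 lower), 11 between R287Q and KO (6 higher, 5 lower) and 18 between R287Q and P32L (11 higher, 7 lower). Simulations without an effect gave medians of 12, 13 and 12. Slow-fibre genes were higher in R287Q than in P32L for 13 of 13 members (mean 1.19, or 0.63 without P32L replicate 3; 0 over the list alone or over all genes). Heat shock genes were lower for 13 of 13 (mean -0.73, 8 over the list alone, 0 over all genes) and immediate-early genes for 18 of 18 (mean -0.90, 8 over the list alone, 0 over all genes). For all 3 the adjusted p was 0.651 with an estimated correlation. Macrophage markers were lower in P32L than in KO for 14 of 14 members (mean -0.53, 0 over the list alone and over all genes; adjusted p = 0.954 with an estimated correlation). They were lower in R287Q than in KO for 14 of 14 (mean -0.55, 1 over the list alone, Cd14, and 0 over all genes, with adjusted p = 0.880 by camera with an estimated correlation). The macrophage score was 0.84 in KO replicate 2, against 0.14 and 0.42 in KO replicates 1 and 3. Clock genes were higher in P32L than in KO for 11 of 15 members (mean 0.23; 5 over the list alone, Per1, Per2, Dbp, Ciart and Nr1d2; 0 over all genes), with adjusted p = 0.954 with an estimated correlation and 2.54e-05 by fry's mixed test. With an estimated correlation and by fry's directional test, 0 of the 38 lists were called between lines. Fry's mixed test called 1 list for P32L with KO (clock), 2 for R287Q with KO (clock, adjusted p = 0.00061, and lipid synthesis, adjusted p = 0.0120) and 0 for R287Q with P32L.

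**Figure D4:**
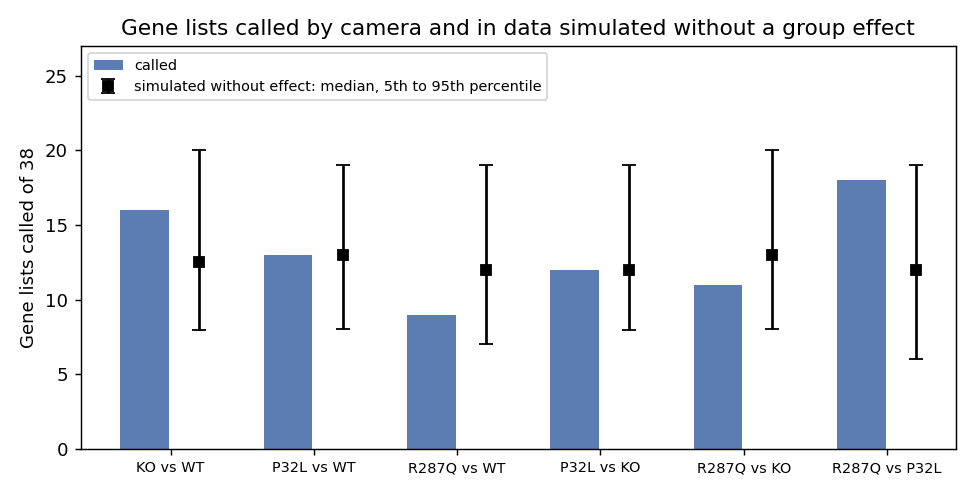
Number of the 38 gene lists called by camera with its preset correlation (bars) in each of the 6 comparisons, beside the median and the 5th to 95th percentile of 100 data sets simulated without a group effect (squares and lines). The counts of 16, 13, 9, 12, 11 and 18 all lie inside these ranges.

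No gene was called in more than 1 of the 3 comparisons with WT. KO and P32L, KO and R287Q, and P32L and R287Q each shared 0 genes called in the same direction. The count is fixed at 0 for both pairs with R287Q, which had 0 called genes. For KO and P32L, independent lists of these sizes would share 0.000328 genes in the same direction. Log2 fold changes of the lines correlated over genes at 0.53 for KO and P32L, 0.44 for KO and R287Q and 0.44 for P32L and R287Q. Because the same WT mice enter each, unchanged groups set against them in simulation gave mean correlations of 0.49, 0.47 and 0.46. The covariances were 0.0222, 0.0167 and 0.0156, against simulated means of 0.0143, 0.0126 and 0.0133. The differences were 0.00788, 0.00403 and 0.00228, and all covariances lie inside the simulated 5th to 95th percentiles. Since 3 WT mice cannot be split into 2 sets of at least 2, the part of any excess due to the shared controls was not separated.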

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

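The tests named here for Cyp26b1, for the clock genes and for reads of Rpl26, and the reading of the splits, were chosen after the result was seen. The predictions for the counts of partitions and for the chromosome 9 test were written before those tests were run. The window of the chromosome 9 test is centred on Rpl26-ps6, which was taken from the calls in these data.

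Cyp26b1 was higher in KO than in every other group: its log2 fold change was -2.24 in P32L against KO and -2.58 in R287Q against KO, which marks the KO mice rather than the WT mice as different. Markers of the 9 tested lists of other cells rose less: the highest median log2 ratio of mean TPM was 0.860 (neutrophil, SD 0.952), against 3.19 for Cyp26b1. This argues against a uniform gain of 1 of these cell types. A subset or state of cells with high Cyp26b1 would not move a list median, so that stays open. Scaling of the libraries is ruled out, as the lowest log2 fold change under the other scalings was 2.16 (2.20 before). The 10 splits of the 6 KO and WT mice count called genes and do not test Cyp26b1 itself.

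Rpl26-ps6 was higher in P32L than in KO by 1.39 as well as against WT. Reads shared with the parent gene are open: the rise of 2.55 TPM is 2.70% of the 94.5 TPM of Rpl26 in WT, too little to show in Rpl26, whose log2 fold change was 0.0687 (SE 0.120). A strain segment around Rpl26-ps6 is open, and the window tested does not reach Gmppb, further along chromosome 9, so a segment that spans both was not tested: within 10 megabases of Rpl26-ps6, 6 of 77 genes (7.79%) had a low p against 572 of 8857 elsewhere (6.46%), one-sided Fisher's exact p = 0.381.

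Gm7846 was lower in R287Q than in KO by -0.84, a call kept in 10 of 14 other settings and 8 of 12 runs that leave out 1 library. Gm10269 was lower by -0.63, kept in 7 of 13 settings and 4 of 12 such runs. Gm43980 was higher by 0.69, kept in 7 of 14 settings and 2 of 12 such runs, with an adjusted p of up to 0.325 in these. For each of these genes the settings that kept the call include weights per library, a fit that stopped before converging.

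Clock genes past the threshold over the list alone in both P32L and R287Q numbered 5: Per1, Per2, Nr1d2, Dbp and Ciart. Of 100 partitions of the 12 mice, the real one included, 2 gave clock genes a mean log2 F as large as the real 1.31 (highest other 1.45). This list was picked from 38 after its values were seen, and with allowance for the picking 17 of 100 partitions gave some list as far above its own mean (real 2.28 SD, highest other 2.96), so chance remains open. With the immediate-early score as a covariate, the mean log2 fold change of the 5 genes was 0.558 in P32L (SE 0.0663, 0.741 before). In R287Q it was 0.572 (SE 0.0483, 0.563 before). These genes were picked from the same data, and the score was itself higher in P32L than in WT (by 0.856). Immediate-early activation at collection therefore stays open for P32L. In R287Q the score was not higher than in WT (difference -0.0436), so the covariate had little to remove there. Another hour of collection could move the same genes and cannot be told apart from genotype, because no hours are given.

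Chance is not excluded for the call counts. Over the 3 comparisons with WT, 6 of 100 partitions called as many genes as the real 5 (median of the others 0, highest 77), and 47 of 100 called as many lists as the real 38 (median of the others 37, highest 49). Among the 10 splits of 6 mice, the number with as many genes was 2 for KO with WT (real 1, highest other 286), 1 for P32L with WT (real 4, highest other 1) and 10 for R287Q with WT (real 0, highest other 20). Between lines it was 2 for P32L with KO (real 2, highest other 2), 1 for R287Q with KO (real 4, highest other 2) and 10 for R287Q with P32L (real 0, highest other 1). Where the real count is 0 the number is fixed at 10, so those comparisons test nothing about chance. For lists the numbers were 2 (real 16, highest other 16), 6 (real 13, highest other 16) and 10 (real 9, highest other 18) against WT. Between lines they were 7 (real 12, highest other 18), 9 (real 11, highest other 16) and 2 (real 18, highest other 18). These 10 splits are too few for a share under 0.05. The 286 genes of the split that set WT replicate 1, KO replicate 2 and KO replicate 3 against the other mice could point to a structure of the samples. The split follows the mitochondrial share, 54.8%, 53.0% and 54.7% in these mice against 56.1%, 58.4% and 57.1% in WT replicates 2 and 3 and KO replicate 1, a match seen afterwards and not tested. Simulations without an effect also gave up to 1109 genes for KO with WT.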

How the results depend on the processing

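Tests with an estimated correlation and fry were planned; the settings marked as added were chosen after the result was seen. The real counts of genes are 1 for KO with WT, 4 for P32L with WT, 0 for R287Q with WT, 2 for P32L with KO, 4 for R287Q with KO and 0 for R287Q with P32L. With the pseudocount at 0.1, R287Q with P32L gave 1 gene. With the pseudocount at 0.01, KO with WT gave 0, P32L with WT 0 and R287Q with P32L 1. With no filter the counts were 20, 13, 34, 21, 43 and 24, the lines shared 7 (KO and P32L), 7 (KO and R287Q) and 8 genes (P32L and R287Q), and the cell cycle list between R287Q and P32L had a mean of -0.0212 with the test in the other direction. With a mean of at least 5 TPM, KO with WT gave 0, P32L with KO 0 and R287Q with KO 2 genes, and R287Q with WT 5 lists. That filter left out Cyp26b1, Rpl26-ps6, Gm17024 and Gm10269, so it did not test their calls. After median-of-ratios scaling the counts were 2 for KO with WT, 23 for P32L with WT, 3 for R287Q with WT, 1 for R287Q with KO (0 higher, 1 lower) and 1 for R287Q with P32L, with 2 genes shared by P32L and R287Q. After quantile normalization they were 3, 28, 1, 1 (0 higher, 1 lower) and 1, with 1 gene shared by KO and P32L, and the mitochondrial genome list between R287Q and KO had a mean of 0.00889 with the test in the other direction. The KO split of 1 higher and 0 lower became 1 and 1 after median-of-ratios scaling and 2 and 1 after quantile normalization. With weights per library, which stopped before converging, P32L with WT gave 25 genes, R287Q with WT 81 genes and 15 lists, R287Q with KO 156 and R287Q with P32L 168 genes, P32L and R287Q shared 6, and the Gmppb log2 fold change turned to 0.00939 in KO and 0.010 in P32L. With only the 2 groups, KO with WT gave 0, P32L with WT 1 and P32L with KO 0. With the replicate number as a block, KO with WT gave 0, P32L with WT 0 and R287Q with KO 1. Of 18 pairs of mice with the same number, 1 correlated above 0.1 in deviations from the group means (-0.53 to 0.24). This shows no pairing by number but cannot exclude it, since the labels give no litter or batch. With an absolute log2 fold change of at least 1, P32L with WT gave 2 and R287Q with KO 1. Of the added settings, mitochondrial genes and nuclear copies left out gave 0 for KO with WT, 0 for P32L with WT and 1 for R287Q with KO, and turned the means of complex I and proteasome genes between R287Q and KO to 0.0112 and 0.00231. Protein-coding genes only gave 2 for P32L with WT, 1 for P32L with KO and 1 for R287Q with KO, with 17 lists for R287Q with KO, and the slow-fibre covariate gave 1 for R287Q with P32L. The protein-coding setting left out Rpl26-ps6, Gm17024, Gm7846, Gm10269 and Gm43980, so it did not test their calls. Camera with an estimated correlation called 0 lists in KO with WT, P32L with WT, R287Q with WT, P32L with KO, R287Q with KO and R287Q with P32L, and so did fry's directional test, 0 in each; its mixed test called 0, 2, 2, 1, 2 and 0.

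Leaving out each library in turn gave 0 (without WT replicate 1 or 3) to 2 genes (without WT replicate 2 or R287Q replicate 2) for KO with WT. For P32L with WT it gave 0 (without WT replicate 1 or 3, or P32L replicate 1 or 3) to 7 (without R287Q replicate 1), with 1 without WT replicate 2 or P32L replicate 2. For R287Q with WT it gave 0 to 1 (without KO replicate 1). For R287Q with KO it gave 1 (without any R287Q replicate) to 5 (without KO replicate 1), with 2 without KO replicate 2, P32L replicate 1 or P32L replicate 2. KO and P32L shared 0 to 1 gene (without WT replicate 2). The Gmppb log2 fold change ran from -0.17 to 0.0431 in KO, from -0.17 to 0.0494 in P32L and from -0.0811 to 0.139 in R287Q, with -0.0296 without R287Q replicate 2 and -0.0395 without R287Q replicate 3. The macrophage list ran from -0.0918 to 0.53 in P32L and from -0.112 to 0.51 in R287Q, lowest without WT replicate 2 and highest without WT replicate 1. Other list means that turned, with their calls lost, were slow-fibre (-0.0832 without KO replicate 2) and tenocyte genes (-0.0106 without R287Q replicate 3) between R287Q and KO, and matrix and fibrosis (-0.00936) and interferon genes (-0.0509) between R287Q and P32L without P32L replicate 3. The interferon mean there also turned without R287Q replicate 2 (-0.0405) and with a mean of at least 5 TPM (-0.0114). Complex I between R287Q and P32L turned to -0.00283 without R287Q replicate 3, with its call kept. With the slow-fibre covariate, the means of lipid synthesis (0.0724) and smooth muscle genes (0.00129) in P32L turned, as did fast-fibre (0.00337) and interferon genes (-0.0700) between R287Q and P32L.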

Other observations

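No test was added for these observations; the lists they use were fixed before the data were examined, and the slow-fibre covariate was chosen after the result was seen.

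Slow-fibre, neutrophil and adipocyte genes varied widely between mice of the same group. The within-group SD of the list score was 1.01 for neutrophil, 0.97 for adipocyte and 0.93 for slow-fibre genes. Over the other lists it ran from 0.04 (mitochondrial genome) to 0.42 (macrophage and monocyte), with 0.08 for clock genes. With the slow-fibre score as a covariate, Cyp26b1 in KO had a log2 fold change of 2.28. In P32L, Per1, Aplnr and Gm17024 no longer passed with it, but their log2 fold changes stayed near those reported over all settings, this one included (1.32 to 1.64, -0.97 to -0.82 and 0.80 to 1.36).

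Measures that would separate these readings are the hour of collection of each mouse, reads over the deleted stretch of Gmppb, and a further set of KO and WT mice for Cyp26b1.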
